A study of Aspergillus niger with 27 samples.

How the data were processed

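The series measured RNA from mycelium of the filamentous fungus Aspergillus niger by RNA sequencing. Colonies were grown in pie-plates, dishes whose wedge-shaped compartments of liquid medium are physically separate and lie under a perforated polycarbonate membrane that lets proteins and metabolites pass but keeps hyphae above it. Per the labels' protocols, each colony was inoculated at the centre of the plate and grew outward over all 9 compartments, and the mycelium over each compartment was excised, frozen and extracted. Compartments 1 to 3 held glucose, 4 to 6 held sugar beet pulp and 7 to 9 held wheat bran. The 3 plates, labelled A, B and C, gave 27 libraries, 1 per plate and compartment. The labels give compartment numbers and not positions on the plate.

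Per the labels' protocols, full-length cDNA was made with the SMARTer Ultra Low RNA kit, fragmented, ligated to barcoded adapters and sequenced on an Ion Proton instrument. The authors deposited whole-number read counts for 11846 gene models in 1 table, with no normalization. HTSeq, a read counter, and DESeq2 are named in the submitters' processing notes without a version or role. The aligner, genome build and gene annotation are not given in the sources used here. Whether the counting used strand, and how it treated reads shared by near-identical genes, is not given either, so counts of overlapping genes and close paralogs are uncertain. The protocols name no molecular identifiers, so precision based on counts covers counting error only. All 27 columns matched the labels of a library, and 0 lines of the table lacked a gene.

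The table names genes by numbered IDs that begin with NRRL3 and does not pair them with gene names. Of the 11846 IDs, 0 were found in the available table of gene names, which belongs to assembly ASM285v2 and numbers its genes by another scheme. Gene lists for the enzymes and pathways of plant polysaccharide use had been fixed before the data were examined, as had the groups, tests, alternatives and the rule for naming genes. The lists could not be joined to these IDs and were not analysed here. The naming rule took, per comparison, genes with an adjusted p under 0.05, a mean log2 CPM of 4 or more and the same direction on all 3 plates, and kept at most 2 IDs that rose and 2 that fell, by size of the fold change. It was applied to the 3 substrate comparisons and to the pair with most calls in each section, and gave 22 combinations of gene and comparison. Genes of pairs with fewer calls were named after their values were seen, as were the 3 most abundant genes.

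Differential expression was computed from the deposited counts with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F-test, TMM factors and the filterByExpr filter for low counts. Since a colony spans all compartments of its plate, the plate is the replicate, and each fit had the plate as a block. For comparisons of substrates, counts were summed over the 3 compartments of a substrate on a plate, which gave 9 sums, 11563 genes after the filter and 4 residual degrees of freedom. For comparisons of compartments, all 27 libraries entered a single fit with 9 groups, which kept 10990 genes and left 16 residual degrees of freedom. Within each section, any difference among its 3 compartments was tested with 2 degrees of freedom, and each pair was tested by itself. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within a comparison, and the threshold was 0.05. Standard errors are the log2 fold change divided by the square root of its F value. CPM were scaled with the TMM factors and are given as mean and SD over plates, and log2 CPM used a prior count of 2.

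The plate block rests on the labels, which place the 9 libraries of a plate in the same colony. As a check, deviations from the compartment means correlated across genes with a mean r of 0.126 over 108 pairs of libraries from the same plate, with 60 pairs over 0.1, and of -0.0624 over 216 pairs from other plates. Deviations from a mean cancel out over the plates, so the value for other plates follows largely from the former and is no separate check. For the sums, the mean r was 0.0908 over 9 pairs from the same plate, from -0.154 to 0.278. No pair of libraries agreed within sampling noise, since the lowest chi-square per degree of freedom was 31.3.

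The tests were tested on simulated data with real means and library sizes. With genes changed in simulated sums of wheat bran against glucose, 22.0% of the 2-fold and 94.9% of the 4-fold changes were recovered, with 10 false calls among 126, over 11507 genes. For compartment 7 against 9, over 10995 genes, 8.0% of the 2-fold and 59.0% of the 4-fold changes were recovered, with 1 false call among 68. The test among compartments 7, 8 and 9 recovered 8.0% and 71.0%, with 1 false call among 80. In these simulations, with 100 genes changed by 2-fold, most of those changes were missed. Where many more genes change, as between wheat bran and glucose, the adjusted threshold is less strict. The shares therefore do not carry over to such comparisons.

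Alternatives were the same fits without the plate block, DESeq2 1.42.0 with the same model, DESeq2 size factors in edgeR, no filter for low counts and leaving out each plate in turn. Substrate comparisons were also run on 1 compartment per substrate, on all 27 libraries in the fit with 9 groups, and with every library thinned to the smallest total of 8006891 counts. For substrates, the fit of 27 libraries takes the 3 libraries of a colony and substrate as separate replicates. Its p-values may therefore be too small where a substrate difference varies between plates. Compartment comparisons were also run with the libraries of a section alone. Further alternatives were chosen after seeing the data. They were substrate comparisons without the compartment 9 libraries, scaling by library size alone, thinning for the compartment comparisons, and sign flips by plate in the test of neighbouring sections. Compartment comparisons were also run with the 64 genes among any library's 20 most abundant left out of scaling and test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.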

Results

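Gene expression was profiled across single colonies of Aspergillus niger that met 3 carbon sources at once, to ask whether parts of a colony express different genes over different substrates and whether a neighbouring substrate matters. Glucose is a simple sugar, sugar beet pulp is a pectin-rich plant residue, and wheat bran is a plant residue rich in arabinoxylan and starch. Each of 3 plates carried 1 colony and gave 9 libraries, 3 per substrate. The labels say that in each substrate section 1 compartment has the same substrate on both sides and the others border another substrate on 1 side, without saying which number is which. Libraries held 12822917 to 19406653 counts on glucose, 12078576 to 20473260 on sugar beet pulp and 8006891 to 24501824 on wheat bran. The lowest totals were in wheat bran compartment 9, with 9565408 ± 2020033 counts (SD, n = 3 plates), against means of 14493188 to 20371915 in the other compartments. Of the 11846 gene models, 22 had 0 counts in all 27 libraries.

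Substrate was the main axis of variation. It accounted for 43.1% of the variance of log2 CPM, compartments within a substrate for 23.0%, the plate for 6.83%, the substrate by plate term for 9.60% and the residual for 17.5%. The first principal component took 44.1% of the variance and placed wheat bran compartment 9 at a mean score of -110 ± 8.12 and sugar beet pulp compartment 5 at 55.2 ± 13.9 (SD, n = 3 plates). Glucose compartments 1 and 3 varied widely between plates on that component, with SDs of 47.6 and 40.02. The shares of the 3 most abundant genes, chosen after their values were seen, differed between substrates. NRRL3_1522 took 9.56% ± 0.623 of the counts on glucose, 4.06% ± 0.437 on sugar beet pulp and 2.96% ± 0.339 on wheat bran. With TMM scaling the order of the plant residues turned for this gene, with 31605 ± 2621 CPM on sugar beet pulp and 36901 ± 1752 on wheat bran, against 97872 ± 6104 on glucose, and wheat bran compartment 9, at 81406 ± 19108, lay above glucose compartment 1, at 76809 ± 29803. NRRL3_1627 took 0.363% ± 0.0240 on glucose, 0.859% ± 0.454 on sugar beet pulp and 3.64% ± 1.32 on wheat bran. NRRL3_1234 took 3.48% ± 0.597, 1.62% ± 0.219 and 5.30% ± 0.551 in the same order (SD, n = 3 plates).

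**Figure D1:**
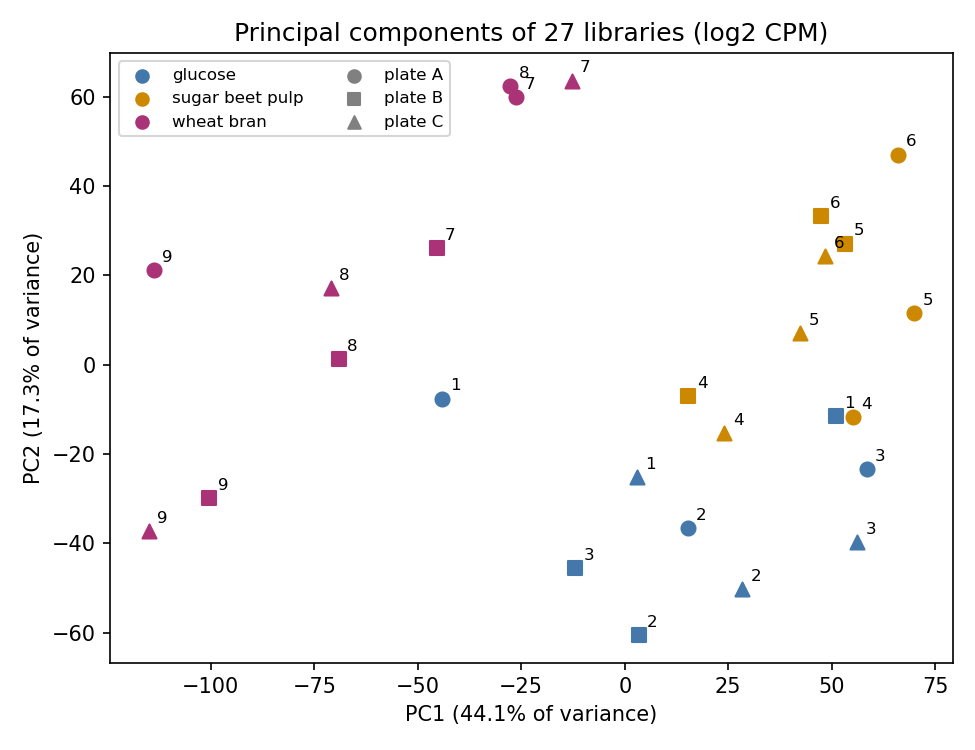
Principal components of log2 CPM for the 27 libraries, with PC1 (44.1% of variance) on the x axis and PC2 (17.3%) on the y axis. Each point is a library, coloured by substrate, shaped by plate and numbered by compartment. The wheat bran compartment 9 libraries lie at the left end, and glucose compartments 1 and 3 change sides on plate B.

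Mycelium on wheat bran differed widely from mycelium of the same colonies on glucose. NRRL3_4008 was nearly silent off wheat bran, at 0.211 ± 0.116 CPM on glucose and 0.166 ± 0.0790 on sugar beet pulp, and reached 163 ± 93.0 CPM on wheat bran (SD, n = 3 plates). Its log2 fold change over glucose was 9.56 (SE 0.301, edgeR quasi-likelihood adjusted p = 4.5e-07 by Benjamini-Hochberg). NRRL3_7876 showed the same contrast, with 0.0630 ± 0.0371 CPM on glucose and 82.8 ± 64.2 on wheat bran. Its log2 fold change of 10.16 (SE 0.49) rests on few counts, because the 9 glucose libraries held 9 counts of it in total and 5 of them held 0. Among genes with a mean log2 CPM of 4 or more, a neighbouring pair of IDs fell most. NRRL3_11179 went from 673 ± 104 CPM on glucose to 12.2 ± 8.59 on wheat bran, a log2 fold change of -5.85 (SE 0.64), and NRRL3_11180 from 114 ± 24.8 to 2.54 ± 0.983, a log2 fold change of -5.51 (SE 0.59). The edgeR quasi-likelihood adjusted p by Benjamini-Hochberg was 4.0e-04 for the former and 3.6e-04 for the latter.

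In all, 3711 of 11563 genes passed the threshold between wheat bran and glucose, 1824 higher and 1887 lower on wheat bran. Of these, 1235 rose and 1038 fell by 2-fold or more. The count was 820 without plate C and 172 with compartments 1, 4 and 7 alone. With scaling by library size alone, which moved the median log2 fold change of all genes from 0.0018 to -0.29, 1176 genes were higher and 3401 lower, while the 4 named genes kept their direction and call.

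Wheat bran and sugar beet pulp, both plant residues, differed in more genes than either did from glucose. NRRL3_1642 and NRRL3_2569 were high on sugar beet pulp and low on wheat bran. NRRL3_1642 stood at 81.7 ± 11.2 CPM on sugar beet pulp, 16.1 ± 5.12 on glucose and 1.78 ± 0.719 on wheat bran, and its log2 fold change from sugar beet pulp to wheat bran was -5.52 (SE 0.40). NRRL3_2569 stood at 422 ± 79.1, 126 ± 70.6 and 13.2 ± 9.18 CPM in the same order, with a log2 fold change of -5.21 (SE 0.41). The edgeR quasi-likelihood adjusted p by Benjamini-Hochberg was 5.7e-05 for NRRL3_1642 and 8.0e-05 for NRRL3_2569. NRRL3_4008 and NRRL3_7876 were again the genes that rose most on wheat bran, with log2 fold changes of 9.88 (SE 0.30) and 10.26 (SE 0.48), the latter against 11 counts in the 9 sugar beet pulp libraries.

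Between these substrates 4854 of 11563 genes passed the threshold, 2344 higher and 2510 lower on wheat bran, with 1632 and 1403 of them at 2-fold or more. The count was 2404 without plate C and 372 with compartments 1, 4 and 7 alone. Scaling by library size alone moved the median log2 fold change of all genes to -0.68 and gave 997 higher and 5737 lower genes, with the named genes keeping their direction and call.

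Sugar beet pulp and glucose were the closest pair of substrates. NRRL3_2664 was 183 ± 91.1 CPM on glucose and 6.93 ± 1.70 on sugar beet pulp, a log2 fold change of -4.73 (SE 0.66). NRRL3_7420 was 70.3 ± 29.7 on glucose and 3.92 ± 2.33 on sugar beet pulp, a log2 fold change of -4.25 (SE 0.45). Both were also low on wheat bran, at 8.54 ± 7.61 and 4.89 ± 2.07 CPM. Their edgeR quasi-likelihood adjusted p by Benjamini-Hochberg was 0.0060 and 0.0027. In the other direction, NRRL3_3278 rose from 1.01 ± 0.193 to 44.8 ± 48.2 CPM, a log2 fold change of 5.04 (SE 0.95), and NRRL3_7460 from 4.75 ± 0.280 to 124.9 ± 46.1, a log2 fold change of 4.59 (SE 0.82). Their adjusted p from the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0157 and 0.0135. The call of NRRL3_3278 was lost without plate A, at a log2 fold change of 4.11, and with compartments 1, 4 and 7 alone, where those of NRRL3_2664 and NRRL3_7420 were lost too. The call of NRRL3_7460 was lost without plate C, at a log2 fold change of 4.79, and with compartments 1, 4 and 7 alone (-0.75) or 2, 5 and 8 alone (2.91), but not with 3, 6 and 9 alone (5.85) or with all 27 libraries in the fit (2.85). The last of these fits takes the 3 libraries of a colony and substrate as separate replicates.

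Sugar beet pulp differed from glucose in 750 of 11563 genes, 266 higher and 484 lower on sugar beet pulp, of which 232 and 366 changed by 2-fold or more. The count was 492 without plate A, 472 without plate B, 83 without plate C, 1214 with DESeq2, 2587 with all 27 libraries in the fit, and 1 with compartments 1, 4 and 7 alone against 1672 with 2, 5 and 8 alone. The 2587 do not rest on more replicates, since libraries of the same colony enter that fit separately. Library size scaling alone gave 1871 higher and 251 lower genes around a median log2 fold change of 0.43, against 0.04 with TMM.

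The genes that set wheat bran apart from glucose were largely also those that set it apart from sugar beet pulp. Of the 1824 genes higher on wheat bran than on glucose, 1416 were also among the 2344 higher than on sugar beet pulp, where independent lists would share 370. Among the genes lower on wheat bran, 1495 were shared where independent lists would share 410. For sugar beet pulp, 123 genes were higher than on both other substrates, against 57.7 for independent lists, and 291 were lower, against 98.1. For glucose, 178 genes were higher than on both plant residues, against 78.99, and 129 were lower, against 42.0. Simulated comparisons with no effect, where few genes are called at all, shared 0 to 0.1 genes on average, which does not show how much of an overlap comes from shared libraries. Comparisons in each overlap share 3 sums, so part of the excess may come from those shared libraries. The fold changes of wheat bran over glucose and over sugar beet pulp had a covariance of 0.851 across genes, against 0.0545 from shared libraries alone in simulation, and an r of 0.83, against 0.51. The fold changes over glucose of the plant residues had a covariance of 0.139 across genes, against 0.0526 from shared libraries alone in simulation. Their r was 0.23, below the 0.50 of that simulation.

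Within the glucose section few genes separated the compartments, and NRRL3_1642, high on sugar beet pulp, was among them. It stood at 35.3 ± 7.81 CPM in compartment 3, against 3.04 ± 2.38 in compartment 1 and 5.62 ± 2.49 in compartment 2 (SD, n = 3 plates). On sugar beet pulp it stood at 93.9 ± 24.6, 71.7 ± 11.7 and 70.1 ± 7.64 CPM in compartments 4, 5 and 6. Its log2 fold change was 3.72 (SE 0.47) from compartment 1 to 3 and 2.79 (SE 0.45) from 2 to 3. NRRL3_6530 was detected mainly in glucose compartments 2 and 3, at 0.698 ± 0.0558 CPM in compartment 1, 19.8 ± 11.5 in 2 and 12.7 ± 5.36 in 3, a log2 fold change of 4.16 (SE 0.57) from 1 to 3. NRRL3_2584, which was high on wheat bran at 4761 ± 2293 CPM, went the other way, with 1389 ± 389 CPM in compartment 1, 152 ± 107 in 2 and 217 ± 144 in 3. Its log2 fold change was -3.35 (SE 0.49) from 1 to 2 and -2.80 (SE 0.48) from 1 to 3. NRRL3_2587 also fell from compartment 1 to 2, from 45.2 ± 16.2 to 15.2 ± 4.25 CPM, a log2 fold change of -1.56 (SE 0.27). The genes of the pairs 1 to 3 and 2 to 3 were named after their values were seen. From 1 to 3, the edgeR quasi-likelihood adjusted p by Benjamini-Hochberg was 6.7e-04 for NRRL3_1642, 0.0011 for NRRL3_6530 and 0.0214 for NRRL3_2584.

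By the edgeR quasi-likelihood F-test, 13 of 10990 genes differed among the glucose compartments. From compartment 1 to 2, 4 genes rose and 2 fell, from 2 to 3 only NRRL3_1642 passed, and from 1 to 3 NRRL3_1642 and NRRL3_6530 rose and NRRL3_2584 fell. DESeq2 called 123 genes among the compartments, 125 from 1 to 2, 3 from 2 to 3 and 38 from 1 to 3, and a fit of the glucose libraries alone called 0 in each. Across genes, the change from 1 to 3 on plate B ran against that on the other plates, with r of -0.53 to plate A and -0.38 to plate C, against 0.68 between A and C. Without plate B, 274 genes differed among the compartments and 1681 from 1 to 3, including all 3 above, while 1 to 2 and 2 to 3 gave 0. Without plate A the counts were 53 among the compartments, 29 from 1 to 2, 7 from 2 to 3 and 27 from 1 to 3, and without plate C all were 0. The calls of NRRL3_2584 and NRRL3_2587 from 1 to 2 were lost on leaving out plate B or C, and that of NRRL3_2587 also without plate A. Of the calls in the pairs ending in compartment 3, that of NRRL3_1642 from 2 to 3 was lost without plate B and that of NRRL3_2584 without plate A. Without the plate block, the calls of NRRL3_2584 in both pairs and of NRRL3_1642 from 2 to 3 were lost, and 8 genes differed among the compartments, 2 from 1 to 2 and 0 from 2 to 3.

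**Figure D2:**
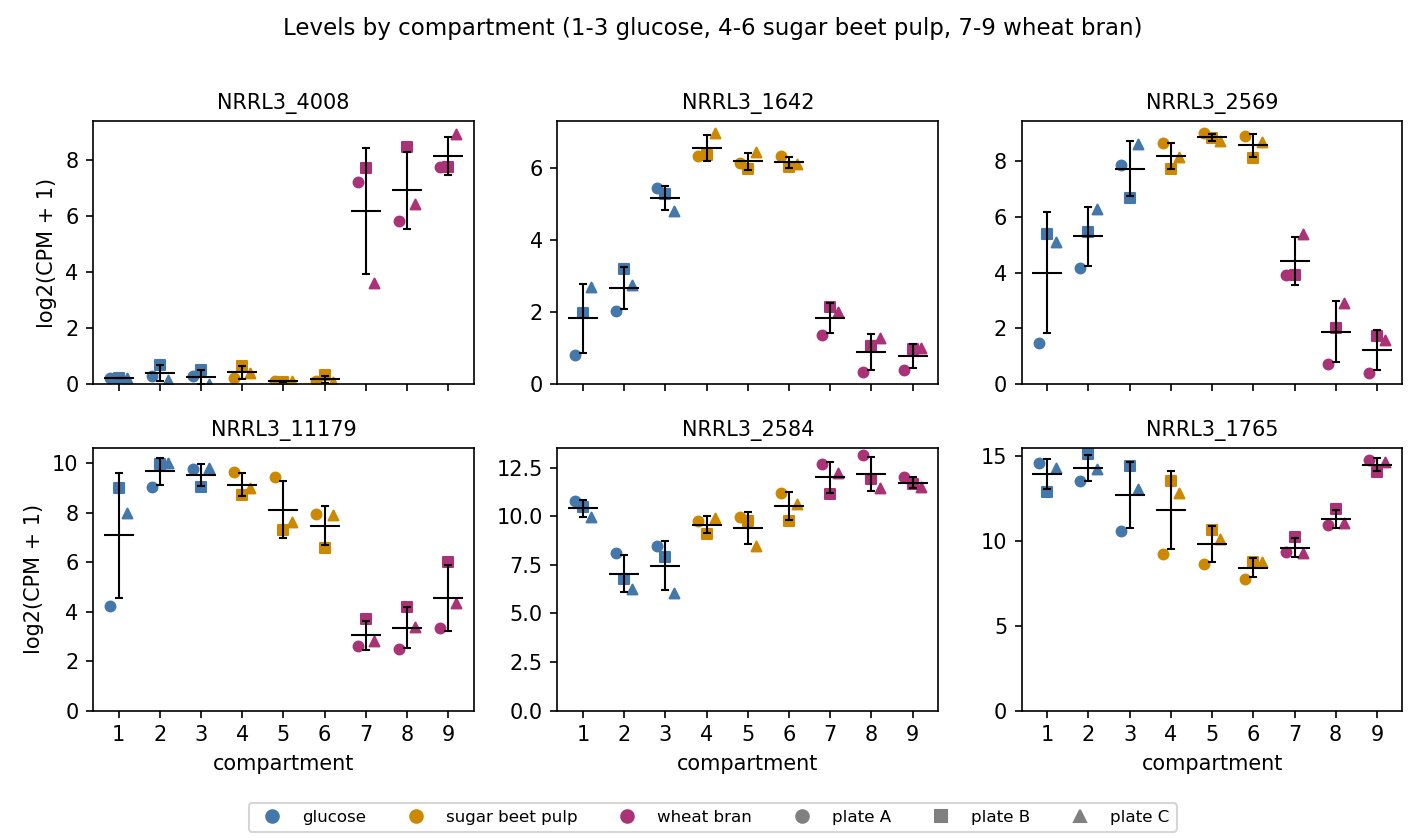
Levels of 6 named genes as log2(CPM + 1) on the y axis against compartment number on the x axis. Points are libraries, coloured by substrate and shaped by plate, and black marks show the mean and SD over 3 plates of the log2 values. NRRL3_1642 stood at 35.3 CPM in glucose compartment 3 and at 3.04 in compartment 1, while NRRL3_4008 stayed near 0 in all glucose and sugar beet pulp compartments.

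In the sugar beet pulp section, compartment 4 stood apart from compartment 6. NRRL3_1765, an abundant gene on glucose at 14902 ± 3813 CPM, went from 6495 ± 5596 CPM in compartment 4 to 1048 ± 619 in 5 and 362 ± 127 in 6, a log2 fold change of -3.90 (SE 0.77) from 4 to 6. NRRL3_1699 went from 1136 ± 972 to 43.4 ± 23.7 and 28.5 ± 16.1 CPM, a log2 fold change of -4.82 (SE 1.10). The neighbouring IDs NRRL3_7459 and NRRL3_7460 rose along the same order. NRRL3_7460 stood at 3.27 ± 0.208, 48.9 ± 33.0 and 290.3 ± 149 CPM in compartments 4, 5 and 6, and at 680 ± 698 in wheat bran compartment 7. NRRL3_7459 stood at 2.08 ± 0.476, 14.1 ± 7.55 and 59.7 ± 9.23 CPM. From 4 to 6 their log2 fold changes were 6.23 (SE 1.26) and 4.98 (SE 0.94), and the edgeR quasi-likelihood adjusted p by Benjamini-Hochberg ran from 0.0072 to 0.0251 over the 4 genes.

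Among the sugar beet pulp compartments, 96 of 10990 genes differed by the edgeR quasi-likelihood F-test. From 4 to 6, 75 rose and 80 fell, from 4 to 5, 1 rose and 13 fell, and from 5 to 6 no gene passed, with 142 at an unadjusted p under 0.05 and 0 with DESeq2. The 142 are fewer than the share of 0.05 of 10990 genes that no difference would give. The spread in this fit came from all 27 libraries, and this section alone gave far higher counts, listed next. Low counts here therefore do not show that the compartments are alike, and counts of different sections are not directly comparable. Counts for the F-test, 4 to 5 and 4 to 6 were 31, 6 and 42 without plate A, 41, 0 and 75 without plate B, 1, 0 and 0 without plate C, 43, 6 and 78 without the plate block, 219, 42 and 360 with DESeq2, and 1134, 529 and 2152 with the sugar beet pulp libraries alone, where 4 genes passed from 5 to 6. All 4 named calls were lost without plate C, those of NRRL3_1699 and NRRL3_1765 also without plate B, and that of NRRL3_1699 also without the plate block. Scaling by library size alone gave 72 higher and 36 lower genes from 4 to 6, around a median of 0.28, and 0 higher and 4 lower from 4 to 5.

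Wheat bran compartment 9 differed widely from the other wheat bran compartments. NRRL3_1765 rose from 822 ± 331 CPM in compartment 7 to 2614 ± 1017 in 8 and 23794 ± 5952 in 9, a log2 fold change of 5.07 (SE 0.81) from 7 to 9. NRRL3_1699 rose from 281 ± 358 to 8612 ± 6601 CPM from compartment 7 to 9, a log2 fold change of 5.38 (SE 1.13). Both of these genes had fallen from compartment 4 to 6 on sugar beet pulp. NRRL3_701 fell from 69.6 ± 76.9 CPM in compartment 7 to 4.12 ± 2.45 in 8 and 1.54 ± 1.29 in 9, a log2 fold change of -5.54 (SE 1.16), and NRRL3_3278 from 57.6 ± 44.3 to 3.09 ± 4.55 from 7 to 9, a log2 fold change of -4.99 (SE 1.18). The edgeR quasi-likelihood adjusted p by Benjamini-Hochberg was 8.1e-05 for NRRL3_1765 and from 8.0e-04 to 0.0022 for the others. These 3 other calls were lost without plate C, where the log2 fold changes were 4.43 for NRRL3_1699, -3.38 for NRRL3_701 and -2.89 for NRRL3_3278. Without plate A those of NRRL3_701 and NRRL3_3278 were -6.49 and -6.93, and the compartment 9 library of plate C held 0 counts of NRRL3_3278, so that its fold change depends on the prior count. The most abundant gene there, NRRL3_1234, reached 187999 ± 55580 CPM in compartment 9, against 39333 ± 11360 in compartment 7.

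By the edgeR quasi-likelihood F-test, 3558 of 10990 genes differed among the wheat bran compartments. From 7 to 9, 2006 rose and 2327 fell, and from 8 to 9, 1192 rose and 1419 fell. From 7 to 8 no gene passed, with 620 at an unadjusted p under 0.05 and 8 with DESeq2. The 620 lie a little above the share of 0.05 of 10990 genes that no difference would give. The compartment 9 libraries also differed as libraries. Their TMM factor was 0.551 ± 0.0954, against 0.947 ± 0.0804 in compartment 7, their 20 most abundant genes took 40.01% ± 4.24 of the counts, against 25.8% ± 1.64, and 8646 ± 530 genes had 10 or more counts, against 10440 ± 64.1 (SD, n = 3 plates). Without plate C the counts were 383 for the F-test, 960 from 7 to 9 and 155 from 8 to 9, and without plate A 1116 from 8 to 9. Scaling by library size alone gave 638 higher and 4253 lower genes from 7 to 9, around a median of -0.84, and 302 higher and 2625 lower from 8 to 9, around -0.61. The substrate comparisons run without compartment 9 called 2935 genes between wheat bran and glucose and 4271 between wheat bran and sugar beet pulp.

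**Figure D3:**
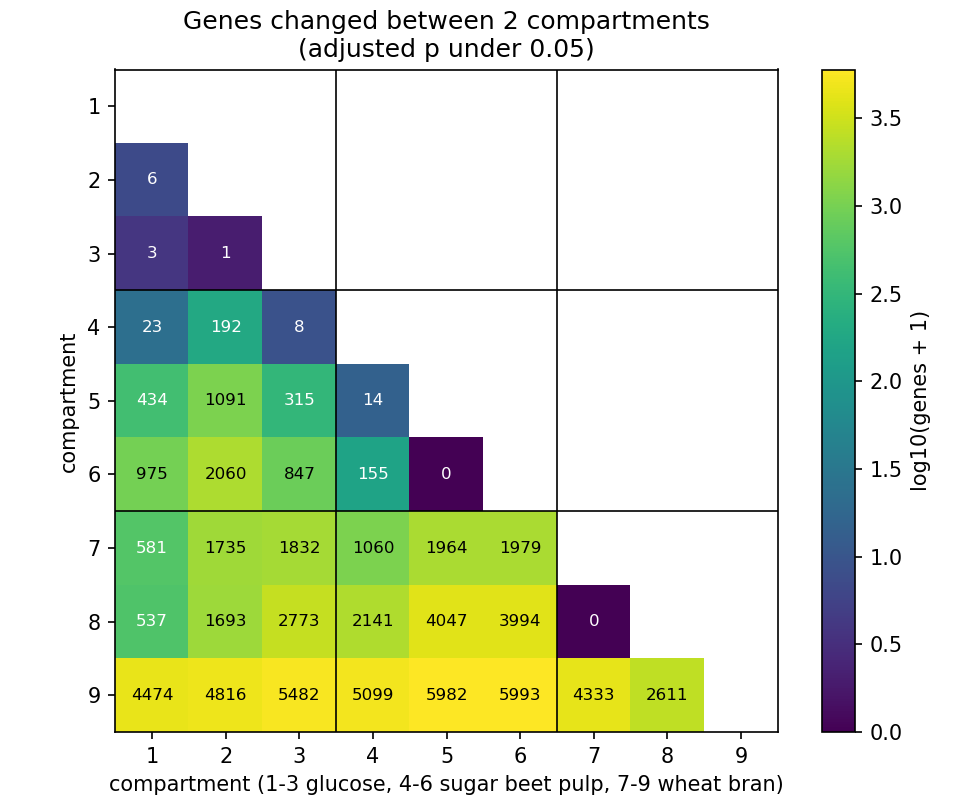
Number of genes with an adjusted p under 0.05 between each pair of the 9 compartments, whose numbers stand on both axes, with colour as log10(genes + 1). Lines part the glucose, sugar beet pulp and wheat bran sections. Pairs with compartment 9 had 2611 to 5993 genes, and compartments 3 and 4, on different substrates, had 8.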

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

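The tests of whether a substrate difference depends on the compartment, the tests of exchanged labels and of reversed numbering on plate B, with the 4-fold changes added last, the slopes from compartment 8 to 9, and the thinned and abundant-gene versions of the compartment comparisons were chosen only after the results they bear on were seen.

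With all 3 plates, the difference between substrates depended for some genes on which of the numbered compartments were compared. Contrasts with wheat bran include compartment 9, which differed from compartment 7 in 4333 genes. Their counts may therefore largely repeat that difference, which was not separated here. Matching the compartments of each section by their order of number, an interaction test in the edgeR fit of 27 libraries found 80 of 10990 genes whose difference between sugar beet pulp and glucose changed with the compartment, 2000 for wheat bran against glucose and 2778 for wheat bran against sugar beet pulp. Without plate C these counts were 0, 14 and 0. Without plate A they were 74, 384 and 2237, and without plate B 12, 3064 and 2125. Without the plate block the first count was 23. In 25 groupings of each section's libraries into 3 compartments, the real grouping included, 1 of 25 gave as many genes in each of the 3 tests, the real grouping. That is the smallest share that 25 groupings can give. Libraries were also dealt without regard to plate, while the real compartments hold 1 library per plate, so these groupings do not decide on chance. The highest counts among the other groupings were 18, 1915 and 1766, and the second of these lies close to the real 2000. A drawn grouping can keep libraries of a compartment together, so a close count does not show what chance gives either.

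Other splits of the samples were counted for each comparison. With 3 sums against 3, or 3 libraries against 3, there are 10 splits, too few for a share under 0.05. For the substrate comparisons 1 of 10 splits, the real one, gave as many genes. The real counts were 750, 3711 and 4854, and the highest other count was 0 in each, among splits that part all 3 plates and among those that part fewer. The same held for the pairs 1 to 2, 2 to 3, 4 to 5, 4 to 6 and 8 to 9, with real counts of 6, 1, 14, 155 and 2611 and a highest other count of 0. For 7 to 9 the real count was 4333 and the highest other 7. For 5 to 6 and 7 to 8 the real count was 0, so that all 10 splits gave as many, and for 7 to 8 a split that parts a single plate gave 920. For 1 to 3 the real count was 3 and 2 of 10 splits gave as many. The higher of these, with 3412 genes, parts all 3 plates and has the plate B libraries on the opposite sides, which points to a structure of the glucose samples. Among the 3 compartments of a section, 25 splits were drawn. On sugar beet pulp and on wheat bran 1 of 25 gave as many genes, the real one, with 96 against a highest other of 76 and 3558 against 3302. That is the smallest share 25 splits can give, the splits were drawn without regard to plate, and the highest others lay close. A drawn split can also keep libraries of a compartment together, so a close count does not show what chance gives. Chance therefore remains undecided there. On glucose 7 of 25 gave at least the real 13 genes, with a highest other of 1864, and chance was not excluded.

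Glucose compartments 1 and 3 tended to differ on plate B in the opposite direction to plates A and C, with an r of -0.508 across genes between plate B and the mean of the others. Reversed numbering of the whole plate is argued against by the pairs 4 to 6 and 7 to 9, where the lower of the r of plate B with the other plates was 0.711, and a difference in depth by an r of -0.534 after thinning all libraries to the same total. Exchanged labels on plate B cannot be told apart from a difference between the colonies, which was not tested, since either would give the reversed direction and with it the match of each plate B library with the other number on plates A and C (r of 0.539 for compartment 1 and 0.468 for 3), on which a first bound for an exchange rested and which is no evidence of its own. Of 92 genes that differed 4-fold or more on plates A and C, 7 (7.61%) kept their direction by that size on plate B, above the 2.16% (4 of 185) that went against plate C on glucose with plate B exchanged and the 0 of 95 from 4 to 6 and 0 of 801 from 7 to 9 that went against the other plates on plate B, so the bound set on this share for an exchange was not met. However, 19 of the 92 turned by that size. Only 17 (18.5%) kept their sign on plate B, against 100% from 4 to 6 and 98.1% from 7 to 9. Colonies that differ in some genes could give the 7.61% with exchanged labels too, so an exchange is not excluded.

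Wheat bran compartment 9 stood apart from compartments 7 and 8. Its libraries were shallower, but with every library thinned to the smallest total 4141 genes still changed from 7 to 9, against 4333. That argues against the read total as the whole cause, although the fits already scaled by totals, so that little movement was likely. Abundant genes took more of its counts, but with the 64 genes among any library's 20 most abundant left out of scaling and test the count was 4288. TMM already sets extreme genes aside, so here too little movement was likely. Neither test bears on other differences between the libraries, such as the 8646 ± 530 genes with 10 or more counts in compartment 9, against 10440 ± 64.1 in 7. An influence of the neighbouring glucose section cannot be told apart from another property of compartment 9. The score for a lean toward glucose and away from sugar beet pulp from 7 to 9 was 0.633 ± 0.363 (SD, n = 3 plates) and above 0 on 3 of 3 plates, which met the bound set for it beforehand, yet from 8 to 9 the slope toward glucose was 0.0810 ± 0.0952, within its spread, and that toward sugar beet pulp was -0.396 ± 0.302.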

How the results depend on the processing

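Scaling by library size alone, the fits without compartment 9, sign flips by plate, and the thinned and abundant-gene versions of the compartment comparisons were chosen only after seeing the data. Named genes were picked from these same data because they passed the threshold. The naming rule also took large changes with the same direction on all 3 plates. Their kept directions and calls, here and above, were thus largely set by that choice and are no separate support. Of 312 values of named genes under the alternatives, 274 kept their direction and their side of the threshold, 37 kept only the direction, 14 of them without plate C, and 1 was reversed. That was NRRL3_7460 between sugar beet pulp and glucose, at -0.75 with compartments 1, 4 and 7 alone. The causes were not tested, except that leaving out a plate leaves fewer samples. DESeq2 size factors in edgeR and dropping the filter kept all 15 counts of genes within 1.5 times. Counts below are in the order of the 3 substrate comparisons (sugar beet pulp against glucose, wheat bran against glucose, wheat bran against sugar beet pulp), the tests among compartments, and the pairs.

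Removing the plate block that pairs the libraries kept the substrate counts within 1.5 times, at 618, 3494 and 4665. It gave 8 genes among the glucose and 43 among the sugar beet pulp compartments, and 2 for the pair 1 to 2, 0 for 2 to 3, 6 for 4 to 5 and 78 for 4 to 6. DESeq2 gave 1214 genes between sugar beet pulp and glucose, 123 among the glucose and 219 among the sugar beet pulp compartments, and 125, 3, 38, 42, 360 and 8 for 1 to 2, 2 to 3, 1 to 3, 4 to 5, 4 to 6 and 7 to 8. Compartments 1, 4 and 7 alone gave 1, 172 and 372 genes in the substrate comparisons, and 2, 5 and 8 alone gave 1672 and 1950 in the first and second. All 27 libraries with 9 groups gave 2587 and 5585 there, in a fit where libraries of the same colony and substrate enter as separate replicates.

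With the libraries of a section alone, the glucose counts were 0 among the compartments and 0 in each pair. The sugar beet pulp counts were 1134 among the compartments, 529 for 4 to 5, 4 for 5 to 6 and 2152 for 4 to 6. Library size scaling alone gave 2122 genes between sugar beet pulp and glucose, 0 for 2 to 3 and 4 for 4 to 5. Thinning gave 5 for 1 to 3, and leaving the abundant genes out gave 7 for 4 to 5.

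Leaving out each plate in turn gave 83 to 492, 820 to 3979 and 2404 to 4201 genes in the substrate comparisons, the lowest each time without plate C. Among the compartments it gave 0 to 274 on glucose, 1 to 41 on sugar beet pulp and 383 to 3097 on wheat bran. For the pairs it gave 0 to 29 for 1 to 2, 0 to 7 for 2 to 3, 0 to 1681 for 1 to 3, 0 to 6 for 4 to 5, 0 to 75 for 4 to 6, 155 to 2295 for 8 to 9 and 960 to 3861 for 7 to 9, with 0 throughout for 5 to 6 and 7 to 8. The neighbour score described under the other observations had a mean of 0.308 with only the genes changed on the other plates, where the exact p was 0.0469 against 0.0625, 0.164 as a rank correlation, with an exact p of 0.246, and 0.225 to 0.492 without each plate. These p-values treat the sections of a plate as independent, and flips by plate gave an exact p of 0.5. Tests of the gene lists were not run, because the IDs could not be joined to names. Depth limits genes such as NRRL3_7876, with 9 counts in all glucose libraries together.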

Other observations

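The tests on neighbouring ID numbers, the counts for pairs of compartments on different substrates, the sign flips by plate and the carry-over values by section were chosen only after seeing the data. The neighbour score was planned.

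Across substrates, the number of genes that separated a pair of compartments depended on which compartments were compared. Glucose compartment 3 and sugar beet pulp compartment 4 differed in 8 of 10990 genes by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and compartments 1 and 4 in 23, while glucose compartment 2 and sugar beet pulp compartment 6 differed in 2060. Between glucose and wheat bran the pairs ranged from 537 genes for compartments 1 and 8 to 5482 for 3 and 9, and between sugar beet pulp and wheat bran from 1060 for 4 and 7 to 5993 for 6 and 9. Leaving out plate C lowered the pair 3 and 4 to 1, 1 and 4 to 3, 2 and 6 to 516, 1 and 8 to 76, 3 and 9 to 2623, 4 and 7 to 104 and 6 and 9 to 3881. Without plate A, 2 and 6 gave 1222, 1 and 8 gave 2138 and 4 and 7 gave 468, and without plate B, 3 and 4 gave 1, 2 and 6 gave 1117 and 1 and 8 gave 204. Which pairs stood at the ends changed as well, since without plate B compartments 1 and 4 also gave 1 gene, and 1 and 6 gave 2731, the most between glucose and sugar beet pulp, while without plate A compartments 5 and 7 gave 416, the fewest between sugar beet pulp and wheat bran. With scaling by library size alone 3 and 4 gave 1, and regrouping of libraries was not run for these pairs. Single genes showed graded levels too. NRRL3_1522, the most abundant gene in 18 of 27 libraries, stood at 59410 ± 6402 CPM in compartment 4, 23212 ± 7528 in 5 and 14212 ± 1608 in 6, and at 24860 ± 3116 in 7, 34981 ± 6185 in 8 and 81406 ± 19108 in 9 (SD, n = 3 plates). NRRL3_2569 stood at 25.5 ± 20.9 CPM in glucose compartment 1, 45.7 ± 30.2 in 2 and 244.7 ± 149 in 3, against 301 ± 95.7 in sugar beet pulp compartment 4.

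Genes with consecutive ID numbers often changed together. Among the 1235 genes at least 2-fold higher on wheat bran than on glucose, 299 pairs had consecutive numbers, against a mean of 129 and a maximum of 165 in 10000 shuffles of the IDs. Among the 1038 at least 2-fold lower there were 186 such pairs, against a maximum of 123. The longest run of higher genes held 10 consecutive numbers, against 8 as the longest in 1000 shuffles, and the longest run of lower genes held 9, against 6. The higher run lay at low levels, with a median log2 CPM of 0.12, while the lower runs of 9 had medians of 2.53 and 7.27. Between wheat bran and sugar beet pulp, 344 higher and 272 lower pairs also exceeded the maxima of 276 and 210, but the longest runs, of 8 higher and 5 lower genes, did not exceed the 8 of the shuffles in either direction. NRRL3_11179 with NRRL3_11180 and NRRL3_7459 with NRRL3_7460 are pairs of this kind among the named genes. A candidate explanation is that substrate-responsive genes lie in clusters along the genome. This is a hypothesis, since positions of these IDs were not used here and reads shared between neighbouring or similar genes were not excluded.

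Outer compartments were tested for a lean toward the substrate they would border if the numbers ran in order around the plate, an assumption the labels do not state. The difference between the outer compartments of a section, regressed across genes on the difference between the substrates they would border on the other plates, had a mean slope of 0.320 over 9 values, 8 of them above 0, with a two-sided exact sign-flip p of 0.0625, but the 3 values of a plate share a colony, and flips by plate gave an exact p of 0.5, where 8 flips cannot go below 0.25, so an influence of the neighbouring section remains undecided. A rank correlation gave a mean of 0.164 with 6 of 9 values above 0 and an exact p of 0.246, and the mean was 0.241 without plate A and 0.225 without plate C, with 5 of 6 values above 0 and exact p of 0.344 and 0.25, against 0.492 without plate B, whose glucose value was -0.472, with 6 of 6 and 0.0312, the smallest that 64 flips can give. Mycelium or RNA carried over when the compartments were sampled may add to such a lean. Genes 4-fold or more lower in the neighbour dropped by a log2 of -0.46 ± 0.19, as the mean and SD over 3 plates of the median of a plate's outer libraries. The carried share allows -0.05 ± 0.01 by the same summary. However, the share was estimated against the neighbour's second-numbered compartment, from 7 to 84 genes per library, and not against the bordering compartment. These can differ, as NRRL3_7460 did with 3.27 CPM in compartment 4 and 48.9 in 5. A share estimated too low makes the limit too small, so carry-over as the whole cause was not excluded. By section, with the mean of a plate's outer libraries, the drop went beyond this limit on glucose, at -0.88 ± 0.29 against -0.06 ± 0.01. On sugar beet pulp (-0.31 ± 0.23 against -0.12 ± 0.12) and wheat bran (-0.33 ± 0.44 against -0.09 ± 0.06) whether it did cannot be told, because the plates varied widely. In addition, 4 of 18 libraries lay within their limit, 3 of them rising, and the carried share ran from 0% to 29.7%.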
